A study of Mus musculus with 6 samples.

How the data were processed

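Gene expression was measured on 6 one-colour microarrays hybridised with Cy5-labelled RNA from cells sorted out of the hind limb muscles of C57BL/6 mice. Each array holds one of 3 freshly sorted populations (PDGFRa+ mesenchymal progenitors, satellite cells, or a mixture of CD31+ or CD45+ cells) at one of 2 ages (8 to 10 weeks or 24 to 28 months), so there is 1 array per cell type and age, and no replicate within a cell type and age. The labels state that cells from repeated sorts were pooled, and that RNA was amplified with amino allyl nucleotides before labelling. Below, CD31_CD45 stands for the mixed population, which holds endothelial or hematopoietic cells.

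For every array there is a scanner file and 1 column of a shared value table. Per the file headers, the scanner files give the median pixel intensity of each of 27456 spots at 635 nm, merged from 3 scanner gains, and the median intensity of the pixels around each spot. The value table deposited by the authors holds linear intensity, scaled so that the median of each column is 25. Set against the scanner files, each value equalled, with a largest difference of 0.0905, a constant times the spot median less the trimmed mean (5% trimmed) of that array's 2736 blank spots. A cell of the table was empty where the spot lay at or below that trimmed mean plus 2 trimmed SD or carried a bad-spot mark. Of 23473 probes, 20757 to 21671 per array (88.4% to 92.3%) were above this background, which is the measure of depth used here. Both the number of arrays and, for dim genes, the signal limit the precision, and these limits were not compared.

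Log2 values were computed here from the scanner files. Spot medians were corrected with limma's normexp method, with the trimmed mean of the blank spots as the background and an offset of 50, then put on the log2 scale and quantile normalised. Folds on this scale understate differences of dim genes because of the offset. The plan, written before the data were examined, was to use the local background of each spot. Before any test was run, that column was found to follow the signal of its own spot (correlation of logs across spots 0.961 to 0.980, with spots not independent of each other), and subtracting it raised the coefficient of variation of positive control spots from between 8.17% and 11.9% to between 29.2% and 61.9%. The blank spots were used for that reason, and the local background was kept as an alternative. Control and blank spots were left out. Symbols came from the array annotation, updated by Entrez identifier to a mouse reference used for names alone. They named 20690 probes, and the 2783 probes without a name were not used. For the 1283 of 19320 genes with several probes, the probe with the highest mean over the 6 arrays was taken. Genes were tested if above background on at least 2 of the 6 arrays (18371 genes). The files name no genome build, so no coordinates are given.

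A linear model with cell type and age as terms was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom, prior degrees of freedom 1.50). In it, 2 arrays of a cell type differ in age, so age differences that are not shared by the 3 cell types enter the error. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg over the 18371 genes within each comparison, and a gene was called between cell types at an adjusted p under 0.05 with at least 2-fold. A gene was called specific to a cell type if it was higher by both criteria against each of the other 2 cell types. The age effect common to the 3 cell types was the age term of the same model (3 aged against 3 young arrays). Within a cell type, 1 aged array was set against 1 young array with no p-value, and genes were counted if at least 2-fold higher or lower among those above background on the brighter array. Below, "rose" and "fell" are used of tested differences, and "higher" and "lower" of values.

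The 32 gene lists, the comparisons, the alternatives (apart from those said to be chosen after seeing the data) and the rule for naming genes were fixed before the data were examined. Lists were tested with limma's camera (preset inter-gene correlation 0.01, and again with an estimated correlation), adjusted over the 32 lists. The estimated correlation rests on 2 residual degrees of freedom, and with it no list passed in any comparison, the sort marker lists included. Its adjusted p-values are given for completeness and say little for or against a list. Members called over all genes and adjusted over the list alone were counted. Within a cell type, a list was described by the median log2 aged over young of its members and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The naming rule took the sort markers Pdgfra, Pax7, Pecam1 and Ptprc, and also Gdf10. It added, for each cell type, the 10 specific genes with the largest smaller one of their log2 differences, and the 10 highest and 10 lowest age folds among bright genes. The last parts were the genes at least 2-fold the same way with age in all 3 cell types, up to 10 specific genes altered with age in each direction, and 2 to 4 members of a list.

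The procedure was tested on simulated data in which 200 of 18371 genes were changed. Between cell types it recovered 49.3% to 50.7% of genes changed 2-fold and 97.0% to 100% of those changed 4-fold, with 1 to 4 false calls. The share at 2-fold follows from the rule and does not measure power. A call needs an estimate of at least 2-fold, and estimates of such genes fall on either side of it. For the common age effect it recovered 89.6% of genes changed 2-fold, with 14 false calls. Of 100 unshifted simulated lists, 3.0% reached the 97.5th percentile and 5.0% lay at or below the 2.5th, and all lists shifted by 0.5 reached the 97.5th. Simulated genes varied independently of each other, so these shares need not hold for real lists whose members vary together. The simulated noise was normal with the SD that eBayes gave each gene, and no age difference was confined to a cell type. The shares of changed genes recovered may therefore be lower on the real arrays.

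Alternatives changed 1 choice at a time, apart from the authors' value table, which differs in background correction, offset, normalisation and empty cells together. They covered the source of values, the background correction and offset, the normalisation, the filter on dim probes, the probe of a gene, the intensity trend in eBayes, the age or cell type term, the fold threshold, each array left out, the scanner set as a block, and for lists the estimated correlation and fry. The scanner sets are 2 groups of arrays whose headers give different straight-line fits between gains 1 and 2: slopes of 0.465 to 0.466 in young PDGFRa, young satellite and aged PDGFRa, and of 0.477 to 0.478 in young CD31_CD45, aged satellite and aged CD31_CD45. Tables were also read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.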

Results

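RNA was profiled in 3 cell populations sorted from the hind limb muscles of young (8 to 10 weeks) and aged (24 to 28 months) C57BL/6 mice, with 1 array for each cell type and age. PDGFRa+ mesenchymal progenitors are the interstitial cells that can become fibroblasts or adipocytes, satellite cells are the stem cells of the muscle fibre, and the third population (CD31_CD45) mixes CD31+ endothelial and CD45+ hematopoietic cells. The series asked which genes are specific to each population and which change with age. Of 23473 probes, 91.99% were above background in young PDGFRa, 90.5% in young satellite, 91.2% in young CD31_CD45, 88.4% in aged PDGFRa, 91.0% in aged satellite and 92.3% in aged CD31_CD45. Across genes, which are not independent replicates, arrays of 1 cell type correlated at r = 0.985 to 0.992 and arrays of different cell types at r = 0.843 to 0.929. With 1 array per cell type and age there are no replicates. The error of a gene is pooled over the 3 cell types, from the spread of each pair of arrays after the shared age difference is removed. It is moderated across genes by eBayes (median residual SD over genes after moderation 0.06 on the log2 scale). An age difference in 1 pair alone thus enters the error of every comparison.

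Each marker given here was brightest in the population it stands for. Pdgfra (probe M200001112), the receptor used for the sort, read 5700.4 in young and 4149 in aged PDGFRa+ cells, against 7.6 and 60.6 in young and aged satellite cells and 26.8 and 28.4 in young and aged CD31_CD45 cells, in the intensity units deposited by the authors. Pax7 (M400001114), the transcription factor that marks satellite cells, read 1055 and 1361.6 in young and aged satellite cells, was below background in both PDGFRa+ arrays, and read 10.6 and 3.7 in CD31_CD45 cells. Pecam1 (M200001072), which encodes CD31, read 2464.8 and 2450.7 in young and aged CD31_CD45 cells and at most 50.1 on the other arrays. Ptprc (M200009499), which encodes CD45, read 251.7 and 414.6 in young and aged CD31_CD45 cells and at most 4.7 elsewhere. Gdf10 (M200008270), which encodes the bone morphogenetic protein family ligand BMP3b, read 805 in young and 306.5 in aged PDGFRa+ cells and at most 11.5 on the other arrays.

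**Figure D1:**
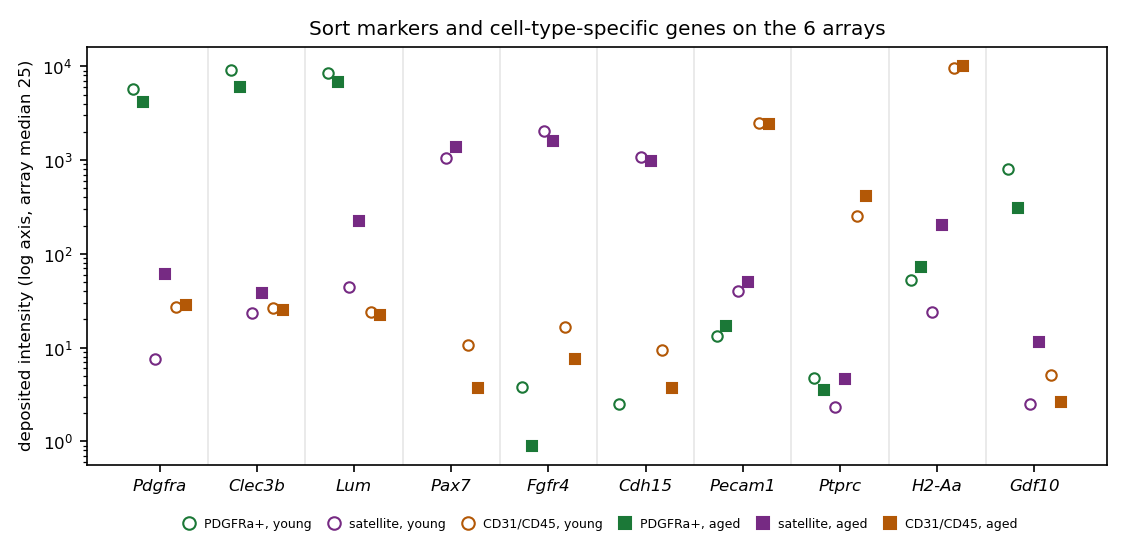
Deposited intensity (log axis, array median 25) of 10 sort markers and cell-type-specific genes on the 6 arrays, with 1 point per array; circles are young, squares are aged, and a missing point lies below background. Pdgfra lies at 4149 and 5700.4 in PDGFRa+ cells and at 60.6 or below on the other 4 arrays, and Gdf10 lies at 805 in young and 306.5 in aged PDGFRa+ cells.

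Against satellite cells, PDGFRa+ cells were rich in transcripts of the connective tissue. Clec3b, which encodes the secreted protein tetranectin, was higher by 6.95 (SE 0.24, log2, adjusted p = 0.00446), Pdgfra by 6.34 (SE 0.47, adjusted p = 0.00920), and Lum, which encodes the collagen-binding proteoglycan lumican, by 5.81 (SE 0.60, adjusted p = 0.0146), each over 2 arrays per cell type. Of the 20 measured mesenchymal progenitor markers, 20 rose, and 20 adjusted over the list alone (camera adjusted p = 2.50e-13; adjusted p = 0.456 with an estimated correlation). In the opposite direction lay genes of the myogenic lineage. Ankrd1, a muscle ankyrin repeat protein, stood at -6.16 (SE 0.27, adjusted p = 0.00549), Myf5, a myogenic transcription factor, at -5.75 (SE 0.16, adjusted p = 0.00392) and Pax7 at -5.18 (SE 0.19, adjusted p = 0.00464). Of 20 satellite cell markers 19 fell, and 19 adjusted over the list alone (camera adjusted p = 4.07e-15; adjusted p = 0.456 with an estimated correlation), and Musk, which encodes a receptor of the neuromuscular junction, was the 1 not called (-0.16).

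Among the matrix lists, 11 of 14 fibrillar and associated collagens rose between these cell types, and 13 adjusted over the list alone, with Col1a2 at 3.85 and Col14a1 at 3.48 (camera adjusted p = 5.48e-08; adjusted p = 0.456 with an estimated correlation). Of 28 matrix remodelling genes 12 rose and 1, Timp4, fell, against 17 and 1 adjusted over the list alone (camera adjusted p = 1.88e-06; adjusted p = 0.456 with an estimated correlation). Of 30 muscle trophic factors 8 rose and 2 fell, against 10 and 2 adjusted over the list alone, with Il33 at 3.60 and Igf1, a growth factor for muscle, at 3.13 (camera adjusted p = 0.000131; adjusted p = 0.456 with an estimated correlation). Of 25 genes of the Wnt pathway 8 rose and 1 fell, against 9 and 1 adjusted over the list alone (camera adjusted p = 1.12e-05; adjusted p = 0.456 with an estimated correlation). The members that rose include the secreted Wnt inhibitors Sfrp4 (4.05), Sfrp2 (3.42) and Dkk2 (2.96), and the member that fell is the ligand Wnt4 (-1.76). Gdf10 rose by 3.65 (SE 0.40, adjusted p = 0.0161), and Fst, which encodes the activin antagonist follistatin, by 3.15; their list of 34 TGF-beta and BMP family genes had 8 that rose and 3 that fell, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.0550).

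Satellite cells were higher for 7 further groups. Of 18 myofibre genes 11 fell in PDGFRa+ relative to satellite cells, and 14 adjusted over the list alone, with Actn3 at -3.86 and Acta1 at -3.01 (camera adjusted p = 1.52e-05, fry adjusted p = 0.0765; adjusted p = 0.613 with an estimated correlation). Of 17 Notch pathway genes 4 fell, and 4 adjusted over the list alone: the receptor Notch1 (-2.29) and the targets Heyl (-3.30), Hey1 (-3.14) and Hes1 (-1.52) (camera adjusted p = 0.000987; adjusted p = 0.456 with an estimated correlation). Of 30 immediate-early and dissociation response genes 6 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000181; adjusted p = 0.456 with an estimated correlation). Of 37 cytosolic ribosomal proteins 4 fell, and 4 adjusted over the list alone, the list median being -0.38 (camera adjusted p = 9.92e-10; adjusted p = 0.456 with an estimated correlation). The remaining groups were lower as lists with few members called: 27 cell cycle genes (2 fell; camera adjusted p = 2.16e-07), 34 oxidative phosphorylation genes (0 fell; 0.000845) and 21 endothelial markers (3 fell and 1 rose; 0.0414), with the same counts adjusted over the list alone. With an estimated correlation these were adjusted p = 0.456, adjusted p = 0.456 and adjusted p = 0.664. In all, 1338 of 18371 genes passed, 751 higher in PDGFRa+ and 587 higher in satellite cells. The count was 0 without the young PDGFRa array and 0 without the aged PDGFRa array (7018 genes had an unadjusted p under 0.05 with all arrays), 3055 with the authors' value table, 2210 with an offset of 10 and 69 with the local background.

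Against CD31_CD45 cells, PDGFRa+ cells showed the same mesenchymal signature, opposite vascular and immune genes. Lum stood at 7.17 (SE 0.60, adjusted p = 0.00710), Mfap5, a microfibril protein, at 7.14 (SE 0.71, adjusted p = 0.00945) and Clec3b at 7.07 (SE 0.24, adjusted p = 0.00175). Of 20 mesenchymal progenitor markers 20 rose, and 20 adjusted over the list alone (camera adjusted p = 3.27e-12; adjusted p = 0.418 with an estimated correlation). Gpihbp1, which holds lipoprotein lipase on capillary endothelium, stood at -7.16 (SE 0.16, adjusted p = 0.00103), H2-Aa, an MHC class II chain, at -6.99 (SE 0.56, adjusted p = 0.00650) and Retnla, a resistin-like protein of alternatively activated macrophages, at -6.61 (SE 0.15, adjusted p = 0.00103). Of 21 endothelial markers 19 fell, and 19 adjusted over the list alone (camera adjusted p = 5.95e-16; adjusted p = 0.406 with an estimated correlation), with Vwf (-0.07) and Erg (-0.25) not called. All 17 macrophage and monocyte markers fell, and 17 adjusted over the list alone (camera adjusted p = 5.18e-13; adjusted p = 0.406 with an estimated correlation). Of 14 pan-hematopoietic markers 13 fell, and 13 adjusted over the list alone (camera adjusted p = 8.33e-11; adjusted p = 0.418 with an estimated correlation).

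Groups beyond the sort markers divided PDGFRa+ from CD31_CD45 cells as well. Of 18 antigen presentation genes 15 fell, and 15 adjusted over the list alone, with H2-Ab1 at -6.95 and Cd74, the MHC class II invariant chain, at -6.06 (camera adjusted p = 8.33e-11; adjusted p = 0.406 with an estimated correlation). Of 26 interferon-stimulated genes 16 fell, and 16 adjusted over the list alone, with Rsad2 at -3.58 and Isg15 at -2.18 (camera adjusted p = 3.39e-10; adjusted p = 0.406 with an estimated correlation). Of 12 pericyte and smooth muscle markers 7 fell and 1, Notch3, rose, against 9 and 1 adjusted over the list alone (camera adjusted p = 0.00258; adjusted p = 0.488 with an estimated correlation). Those that fell include Rgs5 (-4.52) and Acta2 (-4.26). Of 7 tendon markers 5 rose, and 6 adjusted over the list alone, with Thbs4 at 6.70 and Comp at 4.68, both matrix proteins of tendon (camera adjusted p = 0.00743; adjusted p = 0.502 with an estimated correlation). Gdf10 rose by 3.75 (SE 0.40, adjusted p = 0.0112). In all, 1852 of 18371 genes passed, 861 higher in PDGFRa+ and 991 higher in CD31_CD45 cells. No pair of these arrays lies within 1 scanner set. With the scanner set as a block 832 genes passed, 449 higher in PDGFRa+ and 383 higher in CD31_CD45 cells. That block is estimated from the satellite pair alone, where set and age coincide. It therefore does not show which genes would remain without a scanner effect. The count was 1126 without the young PDGFRa array, 3890 with the authors' value table, 2939 with an offset of 10 and 288 with the local background.

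Satellite cells differed from CD31_CD45 cells in myogenic genes on one side and in vascular and immune genes on the other. Chodl, a membrane lectin, stood at 6.01 (SE 0.24, adjusted p = 0.00181), Ankrd1 at 5.87 (SE 0.27, adjusted p = 0.00226) and Nppc, which encodes C-type natriuretic peptide, at 5.74 (SE 0.13, adjusted p = 0.000966). Of 20 satellite cell markers 18 rose, and 18 adjusted over the list alone (camera adjusted p = 8.49e-12; adjusted p = 0.462 with an estimated correlation). Retnla stood at -7.34 (SE 0.15, adjusted p = 0.000894) and C1qb, a chain of complement C1q, at -6.25 (SE 0.04, adjusted p = 0.000751). Of 21 endothelial markers 19 fell (camera adjusted p = 3.56e-15), of 14 pan-hematopoietic markers 13 (8.74e-11) and of 17 macrophage and monocyte markers 17 (7.83e-13), with the same counts adjusted over the list alone. With an estimated correlation these were adjusted p = 0.462, adjusted p = 0.594 and adjusted p = 0.462. Of 18 antigen presentation genes 16 fell (camera adjusted p = 5.14e-11) and of 26 interferon-stimulated genes 17 (8.49e-12), with the same counts adjusted over the list alone and adjusted p = 0.462 with an estimated correlation for both.

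Other groups also separated satellite from CD31_CD45 cells. Of 37 cytosolic ribosomal proteins 5 rose, and 5 adjusted over the list alone, among them Rpl22 (2.15) and Rpl23 (1.98) (camera adjusted p = 1.40e-08; adjusted p = 0.462 with an estimated correlation). Of 22 chemokines 10 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00367; adjusted p = 0.639 with an estimated correlation); Ccl9 stood at -5.12, and Ccl19, a ligand of the lymphocyte receptor CCR7, at 4.93. In this comparison 2145 of 18371 genes passed, 939 higher in satellite and 1206 higher in CD31_CD45 cells. The count was 4616 with the authors' value table, 3375 with an offset of 10 and 342 with the local background.

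By these tests 445 genes were specific to PDGFRa+ cells, 391 to satellite cells and 834 to CD31_CD45 cells. The 10 PDGFRa-specific genes with the widest margin were Clec3b, Pdgfra, Lum, Smoc2, Inmt, Mfap5, Dpep1, Ccn3, Cd248 and Pcolce2, most of them secreted or cell surface proteins of the stroma. For satellite cells they were Ankrd1, Nppc, Erfe, Fgfr4, Myf5, Asb5, Vgll2, Pax7, Cdh15 and Tenm4, which include the lineage factors Pax7 and Myf5, the adhesion molecule Cdh15 (M-cadherin) and the growth factor receptor Fgfr4. CD31_CD45 cells had H2-Aa, Retnla, H2-Ab1, H2-Eb1, Gpihbp1, Cd74, Il1b, Tspan13, C1qb and Timp4, which mix MHC class II and macrophage genes with the endothelial gene Gpihbp1. Without the young and without the aged PDGFRa array the specific counts were 0 for PDGFRa+ and 0 for satellite cells, and without the young PDGFRa array 536 for CD31_CD45 cells. Without the aged CD31_CD45 array 277 were specific to PDGFRa+ cells. With the scanner set as a block, estimated from the satellite pair alone, the CD31_CD45 count was 330.

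The age pair of PDGFRa+ cells had lysozyme genes at its higher and a proteoglycan at its lower end. Lyz2, which encodes the lysozyme of myeloid cells, was highest, at 110.1 in the young and 1904.6 in the aged array (log2 3.79), and its near-identical paralog Lyz1 had 3.37. Cthrc1, a secreted collagen triple helix protein, had 2.74, the C1q-related adipokine C1qtnf3 had 2.03 and Serpina3n, a secreted protease inhibitor, had 1.73. Kera, which encodes the proteoglycan keratocan, was lowest, at 1805 in the young and 196.4 in the aged array (log2 -2.86), followed by the secreted Wnt inhibitor Wif1 (-2.03) and Nrep (-1.83). At least 2-fold, 46 genes were higher and 29 lower of 18011 above background.

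By list, 12 of 14 fibrillar and associated collagens were lower in aged PDGFRa+ cells (median log2 -0.32, 0.0200th percentile of random lists), with Col1a2 at -1.03, Col5a3 at -1.03 and Col6a1 at -0.75. Of 22 basement membrane genes 16 were lower (median -0.24), with Nid2 at -1.09, and of 20 mesenchymal progenitor markers 14 were lower (median -0.21, 0.180th percentile). Matrix remodelling genes had 16 of 27 higher (median 0.26), with Timp1, an inhibitor of metalloproteinases, at 1.49. Antigen presentation genes had 17 of 18 higher (median 0.25), with Psmb8, an immunoproteasome subunit, at 0.69, and senescence and secretory factors had 19 of 24 higher (median 0.25), with Gadd45b at 1.09. Cell cycle genes had 21 of 27 higher (median 0.17) and chemokines 17 of 22 (median 0.18), with Ccl9 at 1.42. Markers of other cells moved in the same pair. All 5 glial markers were higher (median 0.48, 99.99th percentile), Sox10 at 1.65 and Mbp, a myelin protein, at 0.73, and the glial genes Gpr37l1 (2.05) and Pou3f1 (2.53) were among the 10 highest. Endothelial markers had 15 of 21 higher (median 0.06, 99.2th percentile), and myofibre genes 14 of 18 lower (median -0.20, 0th percentile). Macrophage and monocyte markers had a median of 0.08 (99.7th percentile) with 11 of 16 higher, where Lyz2 and Lyz1 alone passed 2-fold, pericyte and smooth muscle markers a median of 0.10 with 8 of 12 higher and 2 at least 2-fold (99.1th percentile), and erythroid genes had a median of -0.47. These are single arrays without a test. Under the alternatives the count was 147 with no background correction, 197 with an offset of 10, and 1089 with the authors' value table, in which 767 were lower. It was 1075 with the local background, which turned Cthrc1 to -1.01, Nid2 to 1.07 and Tsc22d3 to 0.05.

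In the satellite age pair more genes were higher than lower, except with the local background. At least 2-fold, 203 genes were higher and 18 lower of 18184 above background. Cxcl13, a chemokine for B cells, was highest, at 2.9 in the young and 260.6 in the aged array (log2 3.06), followed by Aspn, which encodes the matrix proteoglycan asporin (2.76), Lyz2 (2.55), Lyz1 (2.54), the inflammatory caspase Casp4 (30.9 to 324.1), the galectin Lgals3 (37.7 to 355.7) and the eosinophil chemokine Ccl11 (2.42). Lowest were Ddit4, a stress-induced inhibitor of mTOR signalling (-1.75), Arrdc2 (-1.48) and Smc4, a condensin subunit (-1.40). Antigen presentation genes had 16 of 18 higher (median 0.71), with H2-Ab1 at 2.35, and chemokines 17 of 21 (median 0.64), with Cxcl9 at 2.04. Muscle trophic factors had 27 of 30 higher (median 0.25) and cell cycle genes 23 of 27 (median 0.29). The satellite cell markers themselves had a median of -0.15 (4.07th percentile), with Calcr, the calcitonin receptor of quiescent satellite cells, at -0.98.

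Groups of genes from other muscle cells were higher in the same aged satellite array. Of 20 mesenchymal progenitor markers 18 were higher and 7 at least 2-fold (median 0.50, 100th percentile), with Mfap5 at 2.37, Dcn at 2.34 and Lum at 1.80. All 18 myofibre genes were higher and 9 at least 2-fold (median 1.01), with Mybpc2 at 1.34 and Mb, which encodes myoglobin, at 1.31. Of 12 pericyte and smooth muscle markers 6 were at least 2-fold higher (median 1.01), with Kcnj8 at 2.19 and Rgs5 at 1.98, and of 7 tendon markers 4 (median 1.15), with Thbs4 and Comp both at 2.13. Pan-hematopoietic markers had 11 of 14 higher (median 0.08, 99.99th percentile), macrophage and monocyte markers 14 of 17 (median 0.08, 99.97th percentile) with Lyz2 and Lyz1 over 2-fold, and neutrophil markers 9 of 11 (median 0.09, 100th percentile). With 75th percentile scaling these medians turned to -0.13, -0.055 and -0.14, where the median of all genes lay at -0.17. Endothelial markers had a median of 0.01 (86.7th percentile). Leaving out genes called higher in either other cell type, an alternative chosen after seeing the data, 98 genes were higher and 17 lower. The 2 satellite arrays lie in different scanner sets, so that age and scanner set cannot be told apart in this pair; the count was 372 with no background correction, 473 with an offset of 10, 1432 with the authors' value table (988 higher and 444 lower) and 1256 with the local background (591 higher and 665 lower), which turned Mfap5 to -0.86, Ckm to -0.92 and Tsc22d3 to 0.04.

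**Figure D2:**
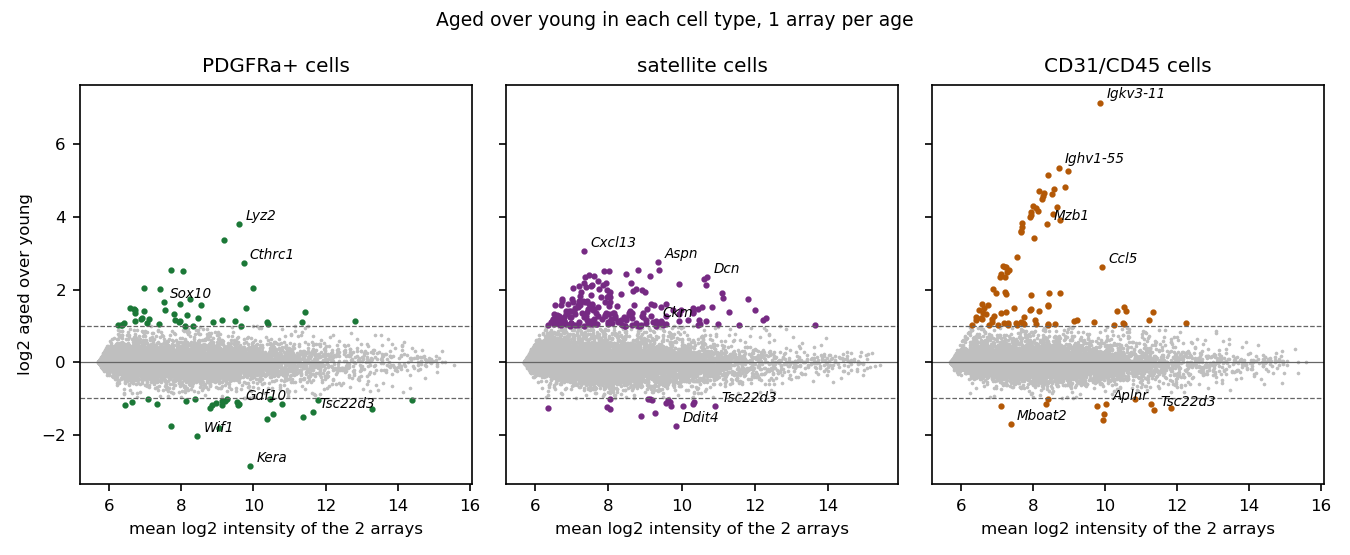
Log2 aged over young against the mean log2 intensity of the 2 arrays, for every gene above background on the brighter array, in each cell type; coloured points are at least 2-fold (dashed lines), and grey points are not. The satellite panel has 203 genes higher and 18 lower, the PDGFRa+ panel 46 and 29, and the CD31_CD45 panel 93 and 12.

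In the CD31_CD45 population the aged array was set apart by immunoglobulin genes. Igkv3-11, a kappa light chain variable gene, read 16.8 in the young and 5606.1 in the aged array (log2 7.15), and Ighv1-55, a heavy chain variable gene, 8.7 and 1644.7 (5.36). All 10 genes at the top were immunoglobulin variable genes, whose probes are too alike to tell single genes apart with certainty. Of 53 measured variable genes 43 were at least 2-fold higher and 0 lower, by the 2-fold rule without a test, and they made up 43 of the 93 genes higher in this pair. Of 9 B and plasma cell markers 9 were higher (median 0.54), among them Mzb1, a chaperone of antibody-secreting cells (3.79), Ms4a1, which encodes CD20 (1.05), and Cd79b (1.04). T and NK cell markers had 13 of 14 higher (median 0.73), with Ccl5 at 2.63 (228.4 in the young and 1462.2 in the aged array), Cd3g at 1.39 and the cytotoxic granule gene Nkg7 at 1.18. Pan-hematopoietic markers had 13 of 14 higher (median 0.51), neutrophil markers 10 of 11 (median 0.35) and antigen presentation genes 14 of 18 (median 0.33).

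Endothelial markers were among the lists that were lower in the aged CD31_CD45 array. Since hematopoietic markers were higher in it, a different mix of CD31+ and CD45+ cells was not told apart from a change within cells. This holds for all age differences of this population. Mboat2, a lipid acyltransferase, was lowest (-1.70), and Ccl21d (-1.59) and Gm1987 (-1.44) are near-identical copies of the lymphatic chemokine Ccl21. The predicted gene Gm10409 had -1.02. Endothelial markers had 15 of 21 lower (median -0.23, 0.0400th percentile), with Aplnr, the apelin receptor, at -1.16, Esam at -0.63 and Kdr, a VEGF receptor, at -0.54, while Sox18 had 0.68. Satellite cell markers had a median of -0.16 with 15 of 20 lower, Chodl at -1.21, glial markers a median of -0.21, and erythroid genes a median of -0.35. At least 2-fold, 93 genes were higher and 12 lower of 18253 above background. This was a comparison of 1 array with 1, and the count was 170 with no background correction, 218 with an offset of 10, 705 with the authors' value table and 915 with the local background, which turned Cxcl1 from -1.21 to 1.69.

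**Figure D3:**
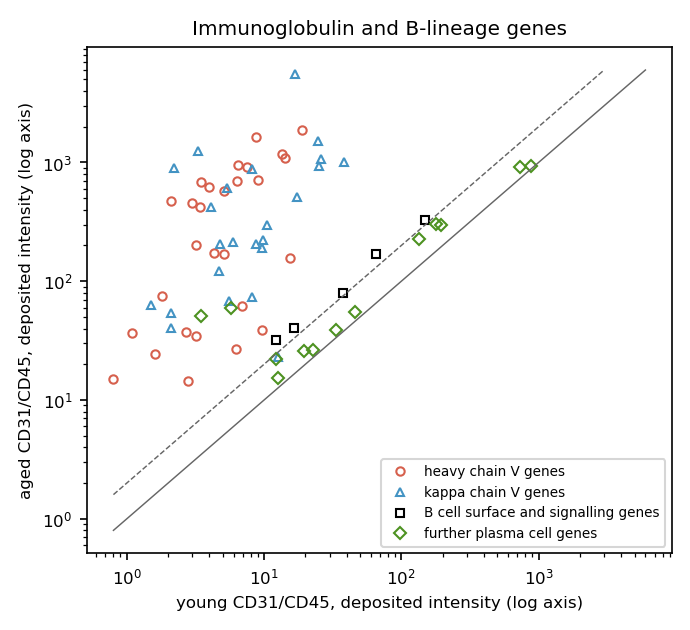
Deposited intensity in the aged against the young CD31_CD45 array (both log axes) for immunoglobulin variable genes, B cell genes and further plasma cell genes, with 1 point per gene; the solid line is equality and the dashed line is 2-fold. Of 53 variable genes, 43 are at least 2-fold higher after normalisation here, and 1 with no value above background in the aged array is not drawn.

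Few of the genes called specific to a cell type were also altered with age in it. The rule works against such genes, since an age difference in a single pair enters the error and makes a gene harder to call specific. In PDGFRa+ cells 3 of 445 specific genes were at least 2-fold higher, namely Rnu3b4 (1.37), the cytochrome P450 gene Cyp1b1 (1.20) and the complement factor Cfb (1.12). Lower were 5: Itm2a (-1.30), Fst (-1.17), Gdf10 (-1.14), the basement membrane protein Nid2 (-1.09) and Col1a2 (-1.03). Gdf10 read 805 in young and 306.5 in aged PDGFRa+ cells, and Fst 788 and 293.2. Altered genes made up 1.80% of the specific and 0.381% of the other genes. In satellite cells 6 were higher, among them the muscle genes Mb (1.31), Ankrd1 (1.21), Tnnt3 (1.15) and Ckm (1.14), and 7 were lower, among them the tachykinin Tac4 (-1.29), the endothelin Edn3 (-1.21), the noncoding RNA Rian (-1.15) and the micropeptide gene Mrln (-1.10), which made 3.32% of the specific and 1.17% of the other genes. In CD31_CD45 cells 14 were higher, among them Ccl5 (2.63), H2-Q5 (1.91, whose probe may also read near-identical H2-Q genes such as H2-Q6), the interferon-inducible Ly6e (1.38) and Psmb8 (1.08), and 4 were lower, Gm1987, Aplnr, Tmem252 (-1.14) and Gm10409, which made 2.16% of the specific and 0.499% of the other genes. Every gene altered at least 2-fold had a brighter signal at or above the median of the genes above background on that array. The shares were not matched on brightness, which alone could set specific genes apart from the others, and they were not tested. For the mixed CD31_CD45 population, a different mix of cells was not told apart from a change within cells. The altered counts rest on the offset and threshold: 37, 49 and 66 genes with an offset of 10 and 0, 0 and 2 at 3-fold, for PDGFRa+, satellite and CD31_CD45 cells. Their direction changed with the settings in PDGFRa+ and satellite cells, while in CD31_CD45 cells more were higher than lower under every setting. In PDGFRa+ cells 20 were higher and 17 lower with an offset of 10, 10 and 7 under 75th percentile scaling, and 13 and 12 with no background correction. More stayed lower there with the authors' value table (18 higher and 40 lower), under median scaling (6 and 8) and at 1.5-fold (29 and 35). In satellite cells 17 were higher and 5 lower under median scaling, 19 and 10 under 75th percentile scaling, 33 and 16 with an offset of 10, and 20 and 40 at 1.5-fold.

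An age difference shared by the 3 cell types was not found for any single gene. Limma called 0 of 18371 genes, with 2025 at an unadjusted p under 0.05 and a lowest adjusted p of 0.324. With 75th percentile scaling, 443 passed, 327 higher and 116 lower, while the other alternatives gave 0. In all 3 pairs, 3 genes differed at least 2-fold in the same direction, and none passed the test. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper GILZ, read 3383.9, 1982.3 and 2510.6 in young and 1339.5, 754.5 and 1009.5 in aged PDGFRa+, satellite and CD31_CD45 cells (log2 -1.30, adjusted p = 0.324). Cxcl13 had a log2 difference of 1.90 (adjusted p = 0.370) and Cfb of 1.44 (adjusted p = 0.324). Gdf10 had -1.14, 0.32 and -0.10 in the 3 pairs and a common difference of -0.31 (adjusted p = 0.778). Across genes, the age folds of PDGFRa+ and satellite cells correlated at r = 0.303, those of PDGFRa+ and CD31_CD45 cells at r = 0.187 and those of satellite and CD31_CD45 cells at r = 0.195, where genes are not independent replicates and each array enters 2 of the 3 values.

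Across the 3 cell types together, 18 lists rose and 1 fell with age by camera with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.587) and 0 by fry. Antigen presentation genes rose as a list (median log2 0.47, adjusted p = 1.22e-09; adjusted p = 0.587 with an estimated correlation), and 0 of the 18 passed over all genes and 8 adjusted over the list alone. The values were 0.44, 0.70 and 0.48 for H2-K1, an MHC class I chain, and 0.50, 0.94 and 0.63 for H2-T23 in PDGFRa+, satellite and CD31_CD45 cells. Cell cycle genes rose as a list (median 0.18, adjusted p = 1.51e-10; adjusted p = 0.587 with an estimated correlation), with 0 of 27 over all genes and 8 adjusted over the list alone. Examples are Cdc20, an activator of mitotic exit, at 0.61, 0.65 and 0.50, and Birc5, which encodes survivin, at 0.48, 0.73 and 0.67. Chemokines rose as a list (median 0.42, adjusted p = 0.000138; adjusted p = 0.587 with an estimated correlation), as did complement genes (median 0.33, adjusted p = 0.00120; adjusted p = 0.587 with an estimated correlation), with 0 and 1 member adjusted over the list alone. Cell type markers rose as lists in the same test: pan-hematopoietic (adjusted p = 0.000416), macrophage and monocyte (0.00191), neutrophil (0.00150), T and NK cell (0.0104), B and plasma cell (0.00898), pericyte and smooth muscle (0.000583), mesenchymal progenitor (0.0341) and myofibre genes (0.00838), each at adjusted p = 0.587 or above with an estimated correlation. T and NK cell markers had medians of -0.006, 0.0004 and 0.73 in PDGFRa+, satellite and CD31_CD45 cells. For B and plasma cell markers they were 0.02, -0.002 and 0.54. Both lists thus rest mainly on the CD31_CD45 pair, whose sort includes hematopoietic cells. A shift in the cells sorted was not separated from a change within cells. Without the aged satellite array, an alternative chosen after seeing the data, 12 lists passed, the adjusted p was 0.0562 for complement genes, and the medians of mesenchymal progenitor markers (-0.066) and myofibre genes (-0.052) turned negative.

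**Figure D4:**
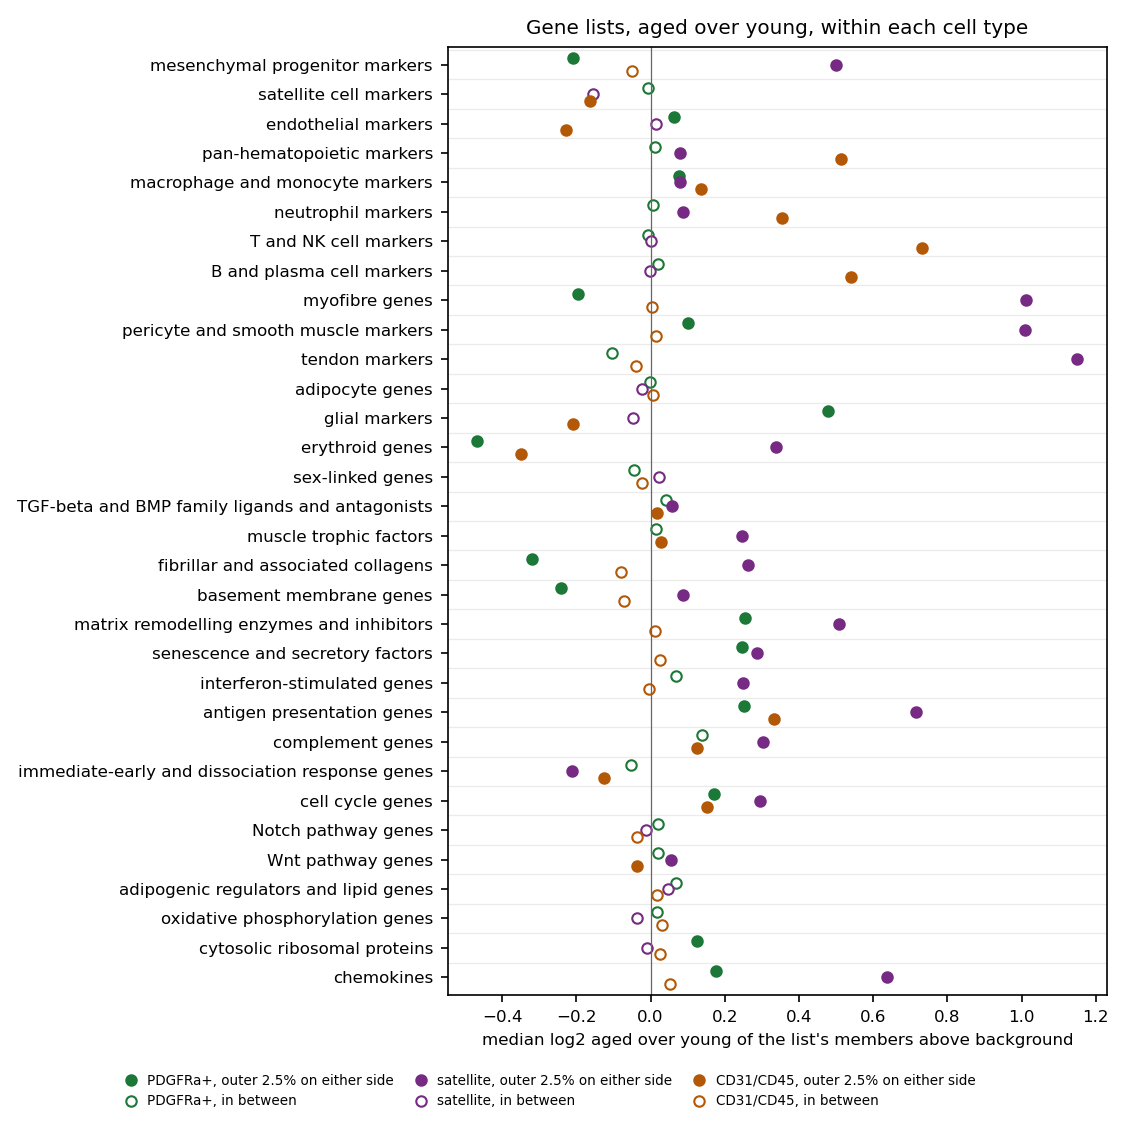
Median log2 aged over young of the members of each of 32 gene lists, in each cell type, with 1 point per list and cell type; filled points lie in the outer 2.5% of 10000 matched random lists on either side, and open points do not. Myofibre genes lie at 1.01 in satellite and -0.20 in PDGFRa+ cells, and antigen presentation genes lie at 0.25, 0.71 and 0.33 in PDGFRa+, satellite and CD31_CD45 cells.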

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

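The tests of carried-over PDGFRa+ cells, of a lower purity, of scan brightness, of more B cells and of a single immunoglobulin transcript were chosen only after the results they measure were seen.

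The following age differences pointed in opposite directions in a pair of cell types, on 1 array per age, and the difference between the cell types was not tested. Chad, which encodes the matrix protein chondroadherin, differed by 2.69 on the log2 scale between satellite (1.25) and PDGFRa+ cells (-1.44). Col1a2, a chain of type I collagen, differed by 2.54 between satellite (1.51) and PDGFRa+ cells (-1.03). List medians that differed between satellite and PDGFRa+ cells were those of myofibre genes by 1.21, erythroid genes by 0.80, mesenchymal progenitor markers by 0.71, collagens by 0.58 and basement membrane genes by 0.33, each higher in the satellite pair. Between PDGFRa+ and CD31_CD45 cells the medians of glial markers differed by 0.69 and those of endothelial markers by 0.29, each higher in the PDGFRa+ pair. The medians of genes of the Wnt pathway differed by 0.092 between satellite (0.05) and CD31_CD45 cells (-0.04), and the satellite value was -0.076 with 75th percentile scaling.

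Of 445 PDGFRa-specific genes, 382 were higher in the aged than in the young satellite array, 63 of them at least 2-fold, such as Dcn (453.6 to 2544). Carried-over PDGFRa+ cells would bring each abundant transcript in a like share of its level in the aged PDGFRa array, and among the 50 abundant genes with a low starting level (under 5% of that level) gains ran from Clec3b (0.242%) to Thbs4 (16.8%). This spread does not decide: 35.9% of 142 abundant genes gained under 2.73% of that level, but this yardstick comes from genes chosen as 2-fold higher, and of the 50 genes of low starting level 9 gained over 4-fold less than their own median of 4.81%. A lower purity that raises all other cell types alike is argued against by median gains of 0.329% for endothelial, 0.379% for pan-hematopoietic, 0.399% for macrophage and 2.19% for mesenchymal progenitor markers (41.5% for pericyte and smooth muscle markers, relative to the CD31_CD45 array, where these cells are not the sorted ones), and scan brightness by the 100th percentile of the mesenchymal list among random lists of like brightness. What stays open is carry-over of PDGFRa+ cells or a subset of them, carry-over of mural cells, a probe-specific difference between the scanner sets, which is confounded with age in this pair, and a change of satellite cells with age, all but the carry-over of PDGFRa+ cells as a whole untested; 140 of the 203 higher genes are not PDGFRa-specific.

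In the aged PDGFRa array all 5 measured glial markers were higher, and a candidate explanation is carry-over of Schwann cells, which the gate on PDGFRa should remove. A further list of 23 measured glial genes, none of them in the other lists, stood at the 100th percentile in this pair, against the 99.4th in satellite and the 16.6th in CD31_CD45 cells, with 16 of the 23 higher. Its more abundant members differed in direction: Art3 from 192 to 419.9, Cnp from 106.6 to 217 and Kcna1 from 62.1 to 194, but Matn2 was lower, from 497.9 to 317.9 and Gap43 from 58.8 to 23.9. All 23 were above background in young PDGFRa+ cells, but so were 91.99% of all probes, and some lay near the floor, such as Gfap (1.1) and Cldn19 (1.9). The source may be other cells or the progenitors themselves, with age untested. The offset and quantile normalisation used here are not the sole source, since the glial list stood at the 99.9th percentile in the authors' value table too. That table rests on the same scans and the same blank-spot background. The local background was not tried for lists within a cell type, so the background correction is not excluded.

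In the aged CD31_CD45 array 43 immunoglobulin variable genes were at least 2-fold higher. In the deposited values these 43 had a median log2 difference of 5.95 (quartiles 4.77 and 6.88). The yardstick thus comes from genes chosen as higher, and the other measured variable genes ran from -0.19 (Igkv7-33) to 5.06 (Ighv1-31). More B cells with unchanged transcripts would raise B cell genes as much. The median of 5 such genes, all also in the B and plasma cell list, was lower, at 1.30. Members at least 2-fold higher lay in 15 variable gene families (5 heavy chain and 10 kappa), which argues against a single transcript read by many probes. Probes may read related transcripts of other families, so a few abundant transcripts read by many probes are not excluded. A candidate source is a greater share of plasma cells, whose CD45 a hematopoietic gate would keep and a sort against the plasma cell marker syndecan would remove. A further list of 13 plasma cell genes stood at the 99.99th percentile with 13 higher, but only Derl3 (3.5 to 50.9) and Eaf2 (5.7 to 59.9) reached 2-fold. Its most abundant members, Ssr4 (873.7 to 933.2) and Sec11c (726.3 to 919.6), are secretory genes that other cells express (all 13 were above background in the young array, as were 91.2% of all probes), and an effect of age or of the B cell clones of the animals used stays open and was not tested.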

How the results depend on the processing

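The local background was the planned correction, and the blank spots took its place after the scanner files were seen, before any test. Chosen only after seeing the data were leaving out genes higher in another cell type and leaving out both satellite arrays. The same holds for 75th percentile scaling for lists within a cell type, and for lists without the aged satellite array. Of 831 alternative values for 93 named age folds, 820 kept their direction and 11 changed it, all 11 with the local background. This agreement is partly by construction. All alternatives read the same arrays, those that change only the filter on dim probes leave a fold as it was, and most of these genes were named for large folds. Of 538 alternative tests of 30 named specific genes, 469 still called the gene and 69 did not: 22 each without the young and without the aged PDGFRa array, 19 with the local background and 6 under other settings. Folds of dim genes near background move with the offset. No paired analysis was possible because the labels give no replicate numbers shared between groups; the model itself compares ages within each cell type. Where an array left out leaves a cell type with 1 array, that array is assumed to vary like the others. With scaling to the 75th percentile the median of all genes lay at 0.25 (PDGFRa+ over CD31_CD45), 0.31 (satellite over CD31_CD45) and -0.17 (age in satellite), with the value table at 0.13 (satellite over CD31_CD45) and -0.18 (age in PDGFRa+), and with median scaling at 0.11 (satellite over CD31_CD45), against at most 0.022 in size with the settings used here. Unless stated, the cause of a change was not tested.

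In the counts that follow, cell type comparisons are PDGFRa+ over satellite, PDGFRa+ over CD31_CD45 and satellite over CD31_CD45, and other triplets are PDGFRa+, satellite and CD31_CD45 cells. The authors' value table, which differs in correction, offset and normalisation together, gave 3055, 3890 and 4616 genes between cell types, 829, 939 and 1510 specific, 1089, 1432 and 705 age folds and 58, 66 and 104 specific genes altered with age. No background correction gave 147, 372 and 170 age folds and 25, 39 and 45 altered. An offset of 10 gave 2210, 2939 and 3375 between cell types, 703 specific to PDGFRa+ and 634 to satellite cells, 197, 473 and 218 age folds and 37, 49 and 66 altered. Median scaling gave 14 altered in PDGFRa+ and 22 in satellite cells. Scaling to the 75th percentile gave 443 genes for the common age effect and 17, 29 and 64 altered. The local background gave 69, 288 and 342 between cell types, 25, 22 and 162 specific, 1075, 1256 and 915 age folds and 2, 0 and 9 altered. With the scanner set as a block, estimated from the satellite pair alone, 832 genes passed for PDGFRa+ over CD31_CD45 and 330 were specific to CD31_CD45 cells. By construction, a 1.5-fold threshold gave 383, 791 and 443 age folds and 64, 60 and 125 altered, and a 3-fold threshold 15, 59 and 47, and 0, 0 and 2. Leaving out genes higher in another cell type gave 115 age folds in satellite cells.

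With each array left out, counts ranged from 0 to 1312 (PDGFRa+ over satellite), 1126 to 1811 (PDGFRa+ over CD31_CD45) and 1730 to 2125 (satellite over CD31_CD45), and specific genes from 0 to 411, 0 to 412 and 536 to 785. The counts of 0 were those without the young or the aged PDGFRa array, 1126 and 536 those without the young PDGFRa array, and without the aged CD31_CD45 array 277 genes were specific to PDGFRa+ cells. The common age effect stayed at 0 in each of these. With an estimated correlation, which has little power at 2 residual degrees of freedom, 0 lists passed in each cell type comparison and 0 for age. Fry gave 0 for age. Lists passing for age were 12 without the aged satellite array, where the medians of mesenchymal progenitor markers (-0.066) and myofibre genes (-0.052) turned negative.

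The local background turned the age folds of Cthrc1 (-1.01), Tubb5 (1.16), Tsc22d3 (0.046), Wfdc1 (0.44) and Nid2 (1.07) in PDGFRa+ cells, of Mfap5 (-0.86), Chia1 (0.43), Gm7819 (1.60), Tsc22d3 (0.036) and Ckm (-0.92) in satellite cells, and of Cxcl1 (1.69) in CD31_CD45 cells. In satellite cells, the medians of pan-hematopoietic markers and neutrophil markers turned to -0.00640 and -0.019 with median scaling and to -0.13 and -0.14 with 75th percentile scaling, which also turned macrophage and monocyte markers (-0.055), TGF-beta and BMP genes (-0.090) and genes of the Wnt pathway (-0.076). Median scaling turned TGF-beta and BMP genes in CD31_CD45 cells to -0.015.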

Other observations

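Leaving out both satellite arrays was chosen only after seeing the data. No other test in this part was chosen only after its result was seen, although the change of Tsc22d3 was noticed in the data before its explanations were written down.

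Secreted signals of the TGF-beta family were split between the cell types. Inhba, which encodes the activin A subunit, was higher in PDGFRa+ than in satellite cells by 2.59 and than in CD31_CD45 cells by 2.65 (log2), beside its antagonist Fst (3.15 and 3.33). Bmp6, a ligand that regulates iron uptake, stood at -1.67 and -1.60 in the same comparisons, and Id1, a target of BMP signalling, at -2.18 and -3.51. Of 9 measured complement genes 4 rose in PDGFRa+ over satellite cells, and 4 adjusted over the list alone, with C1ra at 3.21 and Serping1, the C1 inhibitor, at 1.75 (camera adjusted p = 0.00126; adjusted p = 0.456 with an estimated correlation). Lipid genes went both ways: the adipogenic factor Ebf2 stood at 3.18 over satellite cells, while Pparg (-3.20) and the fatty acid carrier Cd36 (-7.24) were lower in PDGFRa+ than in CD31_CD45 cells. Of the 19 adipogenic and lipid genes 4 rose and 6 fell there, with 4 and 6 adjusted over the list alone (camera adjusted p = 0.913).

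The aged PDGFRa array had higher values of the smooth muscle genes Tagln (79.4 to 204.6) and Acta2 (369.5 to 715.6), whose list of 12 pericyte and smooth muscle markers was higher too (median log2 0.10, 99.1th percentile), of Cd59a, a brake on complement lysis (62.8 to 246.6), and a lower value of Igfbp3 (550.5 to 215). Satellite cells had higher Igf2 (601.1 to 1278.1) and Il6 (59.7 to 271.8). These are single arrays without a test. Interferon-stimulated genes had a median log2 difference of 0.25 in satellite cells, with 16 of 26 higher, against 0.07 in PDGFRa+ and -0.01 in CD31_CD45 cells, and the differences between cell types were not tested.

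Tsc22d3, a classic glucocorticoid target, was lower in the aged array of all 3 cell types. One hypothesis is a lower glucocorticoid response in the aged samples. A separate list of 11 measured glucocorticoid-induced genes stood at the 0.290th percentile in PDGFRa+, the 0th in satellite and the 0.390th in CD31_CD45 cells, as this hypothesis predicts, and Sgk1, Klf9, Per1, Pdk4 and Errfi1 were lower in all 3, but 2, 3 and 4 of the 11 were higher, among them Lcn2 in all 3 and Fkbp5 in CD31_CD45 cells (0.23). At or below the 2.5th percentile lay 5, 1 and 6 of the 32 lists in these pairs. Other causes of a lower level of the glucocorticoid-induced genes stay open, among them handling stress. A different time of day of collection cannot be told apart from this: the median of 9 clock output genes lay at the 18.01th percentile in PDGFRa+, the 12.8th in satellite and the 0th in CD31_CD45 cells. A bound on that median was set beforehand, but 3 of the 9 genes lie near the floor (under 20 on all arrays) and hold it near 0, and the members went different ways. Dbp, Tef and Per3 were lower and Arntl, of opposite phase, was higher in all 3, whereas Nr1d1 was about level (0.00075, 0.07 and 0.05), and the list of opposite phase stood at the 48.3th, 92.8th and 83.8th percentiles. In the same arrays the median log2 difference of immediate-early and dissociation response genes was -0.05, -0.21 and -0.12 in PDGFRa+, satellite and CD31_CD45 cells.

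For the age effect common to the 3 cell types, 3 of the 10 splits of the 6 arrays into 3 and 3, the real one included, gave at least 2025 genes at an unadjusted p under 0.05. The real split gave 2025 and the highest other 2047, and 10 splits are too few for a share under 0.05. Because cell type is in the model, a split that keeps both arrays of 2 cell types together rests on the age pair of the remaining one, so that these splits come in identical twos and are not separate groupings. The value of 2047 is that of the satellite pair: it belongs to the split that follows the scanner sets and to 1 that does not, and so says nothing on the scanner. The scanner set as a block left 1468 genes, as did leaving out both satellite arrays, since the block takes up that pair. In 2 splits 43 genes passed the adjusted p, and both rest on the CD31_CD45 pair, a structure of the samples and not a further result.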
